A study of Rattus norvegicus with 160 samples.

How the data were processed

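Gene expression was measured on 1-colour NimbleGen arrays in the amygdala and hippocampus of male Sprague-Dawley rats at P07, P14, P21 and P75 (adult). Per the labels' protocols, brains were flash frozen and cut into 300 µm sections, each region was dissected from them, and total RNA was converted to double-stranded cDNA, labelled with Cy3 and hybridised. Each of the 32 combinations of region, age and rearing group held 5 arrays, 160 in all. The rearing groups and replicate numbers were taken from the sample titles. Slide positions and hybridisation or scan dates are not given in the sources used here, so batches of arrays were not modelled.

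The deposited values were linear intensities that the authors had made by RMA, per the submitters' processing notes, which name no version or settings. RMA is a method of background correction, quantile normalization and summary of probes. The values showed that the 2 regions had been normalized separately: 22197 transcripts had amygdala values, 25897 had hippocampal values and 22192 had both. Array medians ran from 177.5 to 234.8 in the amygdala and from 114 to 130.4 in the hippocampus, so levels were compared only within a region. The log2 of each intensity was taken here, with no pseudocount and no filter on low values. Arrays report intensity rather than counts, so the number of arrays limits the precision. In the hippocampus the random control sequence averaged 59.3 ± 4.27 (SD over arrays), and 1045 transcripts (4.04%) had a mean at or below it. Within groups, the correlation between arrays across transcripts had a median of 0.94 in the amygdala and 0.906 in the hippocampus, and no 2 arrays held identical values. No column of other samples was present.

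Gene symbols came from an NCBI RefSeq gene table of assembly GRCr8, used for names only. Of 25903 identifiers 9506 matched a gene: 9381 of the 9865 with the prefix NM and 125 of the 16037 with the prefix XM. Transcripts without a match were tested and counted but not named. Dnmt3b had no matched transcript and was not analysed here.

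The 4 rearing groups were LR pups raised by their own LR mother (LR), LR pups fostered to an LR dam (LR-LR), LR pups fostered to an HR dam (LR-HR) and HR pups raised by their own HR mother (HR). Linear models were fitted with limma 3.58.1 in R 4.3.3 to the 20 arrays of each region and age, with 1 mean per rearing group and moderated variances (eBayes). The contrasts were LR-HR minus LR-LR (foster comparison), HR minus LR (line comparison) and LR-LR minus LR (fostering comparison). Models over all 80 arrays of a region gave the foster and line comparisons averaged over ages and the steps between successive ages averaged over rearing groups. At each age, a model of both regions gave the difference of the foster comparison between amygdala and hippocampus. Benjamini-Hochberg adjustment was applied over all transcripts of a fit, and an adjusted p under 0.05 counted as a call. All adjusted p-values of single transcripts come from limma.

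Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Adjustment ran over 248 tests (31 lists in 8 strata) for the foster comparison and over as many for the line comparison. The lists were social and stress neuropeptides, glucocorticoid receptors and target genes, serotonin signalling, dopamine and noradrenaline signalling, GABA signalling, glutamate signalling, DNA methylation and demethylation, histone deacetylases and methyltransferases, growth factors and receptors, immediate early genes, cell cycle, immature neuron and migration, perineuronal net and synapse maturation, mitochondrial respiratory chain, ribosomal proteins, and heat shock and RNA quality. Cell type lists covered myelin and mature oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelial cells and pericytes, choroid plexus, ependyma, meninges and fibroblasts, and blood cells. Lists for neighbouring or dissected regions covered hippocampal neurons, amygdala neurons, thalamus and habenula, striatum and globus pallidus, and hypothalamus. A last list held genes recalled as differing between the bred lines; it came from memory of earlier work that may have used these arrays, so its counts are not independent evidence.

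A line score was the signed mean of the 200 transcripts differing most between HR and LR in a stratum, compared between the fostered groups. These groups entered the choice only by the fit's variance. A maturation score was the mean log2 value of the 200 transcripts that rose most from P07 to P21 minus that of the 200 that fell most, chosen on the LR and HR arrays of a region. LR-HR and LR-LR were compared with an exact two-sided permutation test (252 assignments, smallest possible p = 0.00794), adjusted over 8 strata per score. Named genes were, for each foster and line comparison, the 3 largest called rises and the 3 largest called falls, a panel of 8 genes (Nr3c1, Crh, Oxtr, Avpr1a, Bdnf, Fgf2, Dnmt1, Dnmt3a) whether called or not, and up to 4 called members of each list. The largest changes were named for the other comparisons, and the lowest adjusted p-values for the region differences. The groups, tests, lists and naming rule were set before the data were examined.

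Alternatives were the replicate number as a block (additive within a region, a random block across regions), the mean over all transcripts of a gene in the list tests, only the transcripts above the median of all means, quantile normalization of the arrays of a fit, trend and robust variance, a fit of only the 2 groups compared, other score sizes, and each array or replicate number left out in turn. The labels do not say what a replicate number shares. By the correlation of deviations from group means, every same-numbered pair exceeded 0.1 in 8 of 24 comparisons: the foster comparison in adult amygdala and in hippocampus at P07 and in adults, the line comparison in amygdala at P07, and the fostering comparison in amygdala at P07 and in adults and in hippocampus at P07 and P14. The numbers were taken to pair the arrays there. Score tests ignored the pairs, whose 16 splits allow no p under 0.05, so passes there are uncertain. The median same-number correlation was 0.151, against -0.0411 for other pairs, over 120 pairs. The pairing comes from the data.

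The steps were tested on simulated data. For the foster comparison in amygdala at P14, 42% of 100 transcripts changed by 1 log2 unit and 96% of those changed by 2 were recovered, with 10 of the 22197 transcripts called among the unchanged. For the foster comparison in hippocampus at P21 the shares were 4% and 76%, with 2 such calls. For the line comparison in adult amygdala they were 38% and 96%, with 4 such calls. Recovery was 92% and 100% for the line comparison averaged over ages in amygdala, 11% and 72% for the region difference at P14, and 97% and 100% for the step from P07 to P14 in hippocampus. A simulated shifted list reached a camera adjusted p of 6.49e-14 and 0 other lists were called. The simulated transcripts varied independently, so this does not test list calls where the genes of a list vary together. The permutation test called 4.4% of simulated comparisons without a shift and 98% at a shift of 3 SD. Levels were not compared between regions. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.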

Results

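Transcript levels were measured on arrays in the amygdala and hippocampus of male rats from a pair of selectively bred lines, LR and HR, bred as low and high responders to unfamiliar surroundings. LR pups stayed with their own mother (LR), were fostered to another LR dam (LR-LR) or were fostered to an HR dam (LR-HR), and HR pups stayed with their own mother (HR). Each region was sampled at P07, P14, P21 and in adults, with 160 arrays in all and 5 per group, which limits the precision. Litters are not given in the sources used here, so p-values measure only the spread between these arrays. Changes are log2 values ± SE from limma with Benjamini-Hochberg adjusted p-values, and group levels are mean log2 intensity ± SD over 5 arrays.

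Whether an HR foster dam altered expression in LR pups was asked by comparing LR-HR with LR-LR pups, both of which had been fostered. In the amygdala at P07 few transcripts differed. Nr4a2, an activity-induced nuclear receptor, was 8.95 ± 0.23 in LR-HR and 7.58 ± 0.38 in LR-LR pups (change 1.37 ± 0.18, adjusted p = 0.00483). Egr3, another activity-induced transcription factor, rose by 1.08 ± 0.18 and the vesicular glutamate transporter Slc17a7 by 0.87 ± 0.14 (adjusted p = 0.0188 each). Bmp4, a growth factor of the bone morphogenetic protein family, rose by 1.46 ± 0.25 (adjusted p = 0.022) and the cell cycle regulator Ccng1 by 1.36 ± 0.19 (adjusted p = 0.00483), while Cox6b2, a subunit of cytochrome c oxidase, fell by 0.91 ± 0.15 (adjusted p = 0.0188). The arrays of the groups did not overlap for any of them.

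At P07, 2 of 16 immediate early genes rose (3 adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 0.00472 (adjusted p = 0.335 by estimated correlation). Glutamate signalling rose as a list (median 0.23, 1 of 26 members called, 5 by list alone, camera adjusted p = 0.00382; adjusted p = 0.599 by estimated correlation). GABA signalling (median 0.23) and the immature neuron and migration list (median 0.24) rose with camera adjusted p-values of 0.0395 and 0.0409 (adjusted p = 0.659 and 0.492 by estimated correlation). Ribosomal proteins (median -0.11, camera adjusted p = 0.000584) and the hypothalamus list (median -0.16, camera adjusted p = 0.0105) fell relative to other transcripts, with 0 members called (adjusted p = 0.579 and 0.139 by estimated correlation). In all, limma called 20 of 22197 transcripts, 18 higher and 2 lower in LR-HR pups. The count was 225 without LR-LR replicate 5, 4, 6, 6 and 5 without LR-HR replicates 2, 3, 4 and 5, and 9, 10 and 11 without LR-LR replicates 1, 3 and 4. It was 199 above the median of all means, 150 with trend and robust variance and 0 with only these groups in the fit.

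At P14 GABA and glutamate signalling lists were lower in the amygdala of LR-HR than of LR-LR pups. Own-mother LR pups stood nearer to LR-HR there, with ribosomal protein means of 12.65 in LR, 12.52 in LR-HR, 11.52 in LR-LR and 11.52 in HR pups. Drd2, the dopamine D2 receptor of striatal projection neurons, was 7.57 ± 0.37 against 10.05 ± 0.22 (change -2.48 ± 0.23, adjusted p = 6.75e-07). Cxadr fell by 2.45 ± 0.26 and Dlg2, a postsynaptic scaffold, by 2.20 ± 0.26 (adjusted p = 2.01e-06 and 5.6e-06). Higher levels were found for Krt14, a keratin of basal epidermis (9.07 ± 0.36 against 5.64 ± 0.66), for Ttr, the thyroxine carrier made by choroid plexus (9.50 ± 0.65 against 6.53 ± 0.82), and for the metallothionein Mt3 (12.25 ± 0.18 against 9.73 ± 0.36), with adjusted p-values of 5.35e-06, 7e-06 and 1.61e-07. The arrays of the groups did not overlap for any of these 6 genes.

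By list, 17 of 23 GABA signalling genes fell at P14 and 1 rose (18 and 1 by list alone; median -1.03, camera adjusted p = 4.16e-09; adjusted p = 0.335 by estimated correlation), among them the receptor subunits Gabbr2 (-1.65 ± 0.18) and Gabrb2 (-1.74 ± 0.20). Of 26 glutamate signalling genes 17 fell and 0 rose (21 and 1 by list alone), including Grm7 (-1.73 ± 0.19), Grin2b (-1.84 ± 0.27) and Dlg4 (-1.24 ± 0.18), with a median of -0.79 and a camera adjusted p of 9.91e-08 (adjusted p = 0.225 by estimated correlation). The striatum and globus pallidus list fell in 9 of 13 members (10 by list alone), Adora2a by 1.73 ± 0.21 and Penk by 1.23 ± 0.18 among them; its camera adjusted p was 2.39e-06 and stayed under the threshold with an estimated correlation (0.0151). In 7 of 17 members the perineuronal net and synapse maturation list fell (8 by list alone; median -0.45, camera adjusted p = 0.0376; adjusted p = 0.335 by estimated correlation), Ncan by 1.71 ± 0.18. Ribosomal proteins rose in 22 of 25 members over all transcripts and by list alone (median 0.95, camera adjusted p = 4.93e-17; adjusted p = 0.139 by estimated correlation), Rplp1 by 1.65 ± 0.18. In the mitochondrial respiratory chain list 6 of 21 rose and 1 fell (7 and 2 by list alone; camera adjusted p = 0.00937; adjusted p = 0.599 by estimated correlation), Cox7a2 by 2.02 ± 0.18.

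Not every list moved at P14. Of 27 social and stress neuropeptides 6 rose and 4 fell (7 and 5 by list alone), with Sst at 1.64 ± 0.16, Cck at 1.85 ± 0.19 and Npy at 1.06 ± 0.16 on one side and Penk on the other (camera adjusted p = 0.396). The activity-induced Egr1 fell by 1.68 ± 0.19 (adjusted p = 2.89e-06), the serotonin receptor Htr2c by 1.74 ± 0.34 (adjusted p = 0.000802), and the astrocyte gap junction gene Gja1 by 1.47 ± 0.19 (adjusted p = 1.23e-05). Among markers of blood, the globin genes Hbb-b1 (1.67 ± 0.22) and Hbb (1.22 ± 0.19) rose, as 3 of 7 list members did (camera adjusted p = 0.129). Aif1 and Tyrobp were the 2 of 14 microglial genes that rose (1.13 ± 0.31 and 1.11 ± 0.33; camera adjusted p = 0.446). The count was 4943 transcripts, 1891 higher and 3052 lower.

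**Figure D1:**
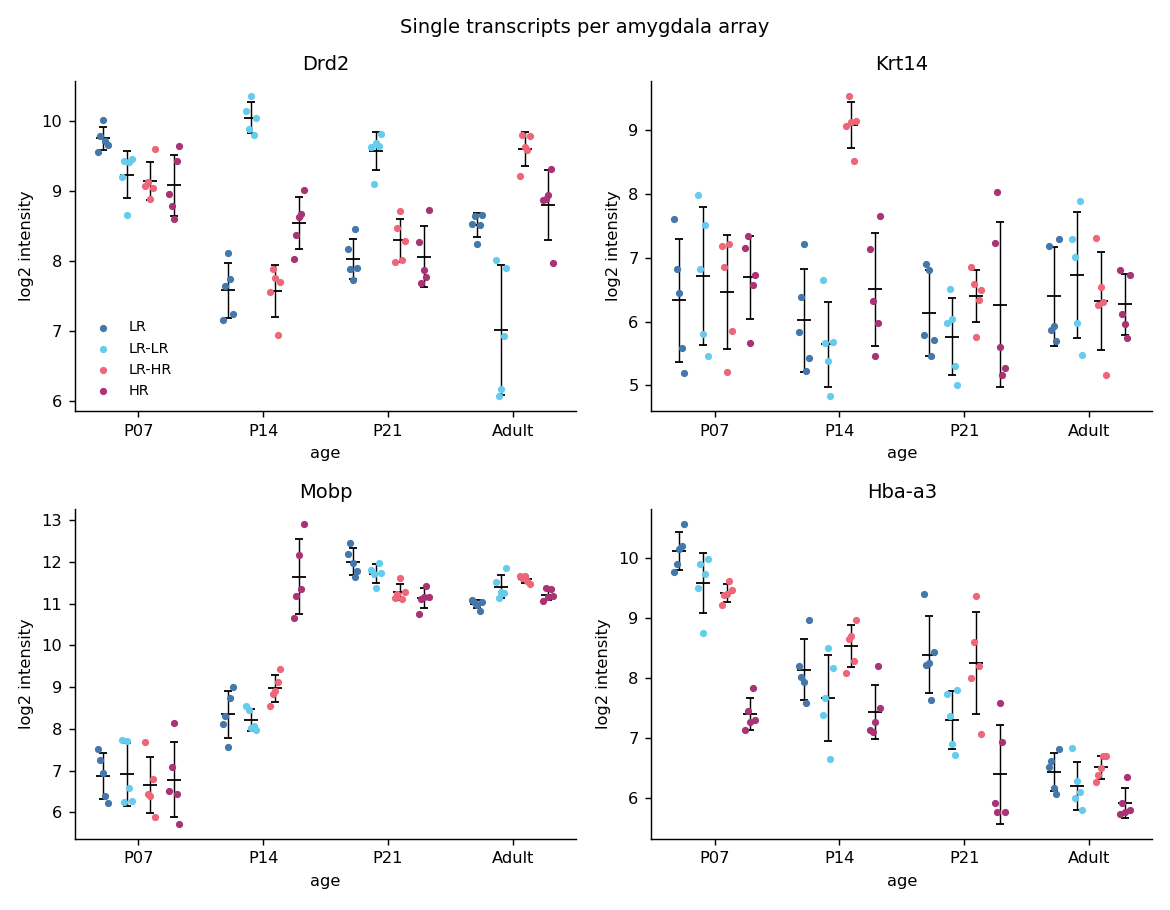
Log2 intensity (vertical axis) of Drd2, Krt14, Mobp and Hba-a3 in the amygdala at P07, P14, P21 and in adults, with 1 point per array and 1 colour per rearing group.

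At P21 LR-HR pups again had lower GABA and glutamate signalling and higher ribosomal protein lists in the amygdala than LR-LR pups. Ribosomal means were 12.29 in LR-HR and 12.11 in HR against 11.37 in LR and 11.38 in LR-LR pups. The acidic ribosomal protein gene Rplp1 was 12.61 ± 0.34 in LR-HR and 10.51 ± 0.20 in LR-LR pups (change 2.10 ± 0.23, adjusted p = 4.45e-06), and Mt3 was higher by 2.09 ± 0.21 (adjusted p = 2.06e-06). Abhd14b fell by 2.01 ± 0.29, Tmem255a by 1.78 ± 0.36 and the endothelial transcription factor Erg by 1.72 ± 0.28 (adjusted p = 7.48e-05, 0.00176 and 0.00024). Drd2 was lower by 1.28 ± 0.23 (8.30 ± 0.31 against 9.58 ± 0.27, with LR at 8.03).

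Ribosomal proteins rose in 20 of 25 members at P21 (21 by list alone; median 0.86, camera adjusted p = 1.46e-19; adjusted p = 0.0876 by estimated correlation). GABA signalling fell in 14 of 23 members (16 by list alone; median -0.69) and glutamate signalling in 15 of 26 (17 by list alone; median -0.77), each with a camera adjusted p of 0.000102 (adjusted p = 0.492 and 0.433 by estimated correlation). Grin2b changed by -1.42 ± 0.28 and Grik2 by -1.40 ± 0.28. Myelin and mature oligodendrocyte genes fell in 6 of 15 members (8 by list alone), Cnp by 0.85 ± 0.17 (median -0.54, camera adjusted p = 0.00692; adjusted p = 0.521 by estimated correlation). Endothelial and pericyte genes fell in 6 of 14 (8 by list alone), Abcc9 by 1.41 ± 0.31 (camera adjusted p = 0.0128; adjusted p = 0.433 by estimated correlation). The mitochondrial list had 8 of 21 members higher, Cox7a2 by 2.08 ± 0.21, and 3 lower (camera adjusted p = 0.00342; adjusted p = 0.515 by estimated correlation).

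Blood cell genes were higher in LR-HR pups at P21 in 3 of 7 members (camera adjusted p = 0.00909; adjusted p = 0.139 by estimated correlation), with Hbb at 14.48 ± 0.30 against 12.56 ± 0.17. The DNA methyltransferase Dnmt3a fell by 0.92 ± 0.20 (adjusted p = 0.00317), the histone deacetylase Hdac1 by 1.20 ± 0.25 (adjusted p = 0.00201) and the serotonin receptor Htr2a by 1.46 ± 0.24 (adjusted p = 0.000231). The count was 4797 transcripts, 1364 higher and 3433 lower (28.4% higher). After quantile normalization of the 20 arrays 44.8% of calls were higher, the median change of all transcripts in the deposited values being -0.15.

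In adults GABA, glutamate, striatal, myelin and astrocyte lists were higher in the amygdala of LR-HR than of LR-LR rats, while ribosomal proteins were not called as a list (median -0.05, camera adjusted p = 0.129). Drd2 was 9.61 ± 0.24 against 7.02 ± 0.92 (change 2.58 ± 0.32, adjusted p = 4.82e-05), Grm5 rose by 2.38 ± 0.35 (adjusted p = 0.000133) and Adora2a by 2.25 ± 0.34 (adjusted p = 0.000194). The transcription factor Gata4 fell by 2.15 ± 0.46, Or10d4c by 1.81 ± 0.50 and Haao by 1.78 ± 0.46 (adjusted p = 0.00252, 0.0134 and 0.00919). The opioid peptide precursors Pdyn (2.10 ± 0.24) and Penk (1.42 ± 0.18) and the peptide gene Cartpt (1.62 ± 0.24) also rose.

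Adult LR-HR rats had 16 of 23 GABA signalling genes higher (20 by list alone) and 0 lower, with a median of 0.95 and a camera adjusted p of 1.22e-08 (adjusted p = 0.335 by estimated correlation); Gad1 rose by 1.12 ± 0.17 and Gad2 by 1.31 ± 0.19. Glutamate signalling rose in 13 of 26 (camera adjusted p = 0.00201; adjusted p = 0.492 by estimated correlation) and the perineuronal net list in 9 of 17 (10 by list alone; camera adjusted p = 0.00725; adjusted p = 0.48 by estimated correlation). The striatum and globus pallidus list rose in 10 of 13 members (median 1.42, camera adjusted p = 4.25e-07), and its call held with estimated correlation (adjusted p = 0.0202). Myelin genes rose in 10 of 15, Ugt8 by 1.18 ± 0.17 and Cnp by 1.07 ± 0.19 (camera adjusted p = 0.000259; adjusted p = 0.335 by estimated correlation). Astrocyte genes rose in 8 of 15 (10 by list alone), Gja1 by 1.77 ± 0.19 and Slc1a3 by 1.73 ± 0.20 (camera adjusted p = 0.00121; adjusted p = 0.508 by estimated correlation).

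Choroid plexus genes fell as a list in adults, 3 of 14 lower and 1 higher (4 and 1 by list alone; median -0.48, camera adjusted p = 0.0254; adjusted p = 0.392 by estimated correlation). Among glucocorticoid-related genes Sgk1 rose by 1.38 ± 0.28 and Errfi1 by 1.28 ± 0.25 (adjusted p = 0.00157 and 0.00116). Among blood markers Hba-a2 rose by 0.77 ± 0.20 and S100a9 fell by 0.90 ± 0.25 (list camera adjusted p = 0.969). The count was 4817 transcripts, 3807 higher and 1010 lower (79.0% higher). After quantile normalization 64.8% were higher, the median change of all transcripts being 0.12.

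**Figure D2:**
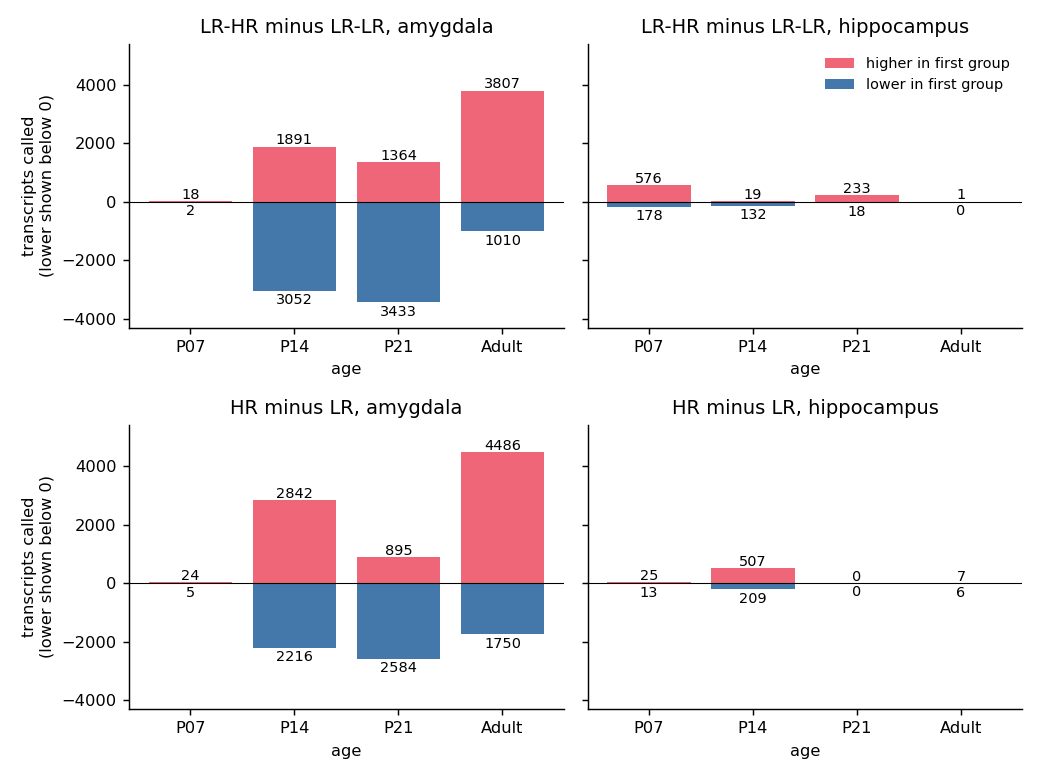
Number of transcripts called higher (bars above 0) and lower (bars below 0) at each age in the foster and line comparisons, with a panel for each comparison and region.

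In the hippocampus at P07 the GABA, glutamate, immature neuron and astrocyte lists were higher in LR-HR than in LR-LR pups, though few members were called. Ctnnb1, beta-catenin, was 10.43 ± 0.28 against 7.92 ± 0.99 (change 2.51 ± 0.33, adjusted p = 0.000175), with LR at 10.03. Zbtb18 rose by 2.49 ± 0.28, Hmgcs1 by 2.29 ± 0.32 and Slc17a7 by 2.07 ± 0.26 (adjusted p = 6.27e-05, 0.000297 and 0.000106). Mnat1 fell by 1.38 ± 0.28, the keratin Krt18 by 1.30 ± 0.28 and Tomm20l by 1.11 ± 0.31 (adjusted p = 0.00545, 0.00992 and 0.049).

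GABA signalling rose in 6 of 23 members (13 by list alone; median 0.79, camera adjusted p = 4.66e-10; adjusted p = 0.335 by estimated correlation) and glutamate signalling in 5 of 26 (12 by list alone; camera adjusted p = 1.22e-08; adjusted p = 0.335 by estimated correlation). The immature neuron and migration list rose in 3 of 16 (4 by list alone), Dpysl5 by 1.81 ± 0.28 and Tubb2b by 1.36 ± 0.24 (camera adjusted p = 8.77e-05; adjusted p = 0.46 by estimated correlation). Astrocyte genes rose in 4 of 15, Slc1a3 by 1.79 ± 0.27 (7 rose and 2 fell by list alone; camera adjusted p = 0.00342; adjusted p = 0.433 by estimated correlation). Of 25897 transcripts 754 were called, 576 higher and 178 lower, and 2263 with the replicate block. The count was 1369 without LR-LR replicate 5, 452 and 414 without LR-HR replicates 3 and 5, and 452, 418, 468 and 444 without LR-LR replicates 1, 2, 3 and 4.

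At P14 hippocampal differences were fewer and mostly downward in LR-HR pups. The ubiquitin ligase gene Rnf44 was 9.32 ± 0.29 against 10.96 ± 0.20 (change -1.64 ± 0.21, adjusted p = 0.00106), and Srebf2 fell by 1.62 ± 0.29 (adjusted p = 0.014). Ccng1 rose by 1.60 ± 0.23, Mrpl47 by 1.33 ± 0.24 and Alad, of haem synthesis, by 1.14 ± 0.24 (adjusted p = 0.00154, 0.0121 and 0.0277). GABA signalling fell in 3 of 23 members (6 by list alone), Gabbr2 by 1.46 ± 0.23 (camera adjusted p = 0.000384; adjusted p = 0.508 by estimated correlation). Glutamate signalling fell in 2 of 26 (5 by list alone; camera adjusted p = 0.000876; adjusted p = 0.492 by estimated correlation), and astrocyte genes fell in 4 of 15, Gja1 by 1.18 ± 0.23 (camera adjusted p = 0.00937; adjusted p = 0.528 by estimated correlation).

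Ribosomal proteins (median 0.32) and the mitochondrial list (median 0.31) rose relative to other transcripts in the hippocampus at P14 with 0 members called (camera adjusted p = 3.38e-06 and 0.00121; adjusted p = 0.599 and 0.608 by estimated correlation). The count was 151, 19 higher and 132 lower. It was 42, 50, 59 and 37 without LR-HR replicates 1, 2, 3 and 4 and 87, 31, 31 and 28 without LR-LR replicates 1, 3, 4 and 5. With only these groups in the fit 5 were called.

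At P21 the myelin, astrocyte and mitochondrial lists were higher in the hippocampus of LR-HR pups, against LR-LR arrays that varied widely. The tubulin gene Tubb2b was 11.18 ± 0.26 against 7.82 ± 2.12 (change 3.36 ± 0.61, adjusted p = 0.0141), Zwint was higher by 3.07 ± 0.75 (adjusted p = 0.045) and Olfm1 by 3.01 ± 0.64 (adjusted p = 0.0315). Hdgfl1 fell by 1.61 ± 0.37 and the cytokine Il7 by 1.54 ± 0.33 (adjusted p = 0.0395 and 0.0315), as did the transcription factor Gata6 (adjusted p = 0.0395). For Il7 3 of 5 LR-HR arrays and for Tubb2b 2 of 5 LR-LR arrays lay at or below the random sequence control of the same array, so the sizes of these changes are uncertain. Hsd11b1, which regenerates active glucocorticoid, rose by 2.11 ± 0.38 (adjusted p = 0.0141) and the astrocyte filament gene Gfap by 2.48 ± 0.41 (adjusted p = 0.00889).

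Myelin genes rose in 4 of 15 members at P21 in the hippocampus (10 by list alone), Mbp by 3.12 ± 0.64 and Mog by 1.76 ± 0.41 (median 1.22, camera adjusted p = 2.71e-09; adjusted p = 0.136 by estimated correlation). Astrocyte genes rose in 3 of 15 (11 by list alone; camera adjusted p = 7.94e-08; adjusted p = 0.335 by estimated correlation) and mitochondrial genes in 3 of 21 (12 by list alone; camera adjusted p = 6.9e-05; adjusted p = 0.133 by estimated correlation). With 0 members called over all transcripts, the GABA (median 0.61), glutamate (0.52), oligodendrocyte precursor (0.94) and endothelial (0.58) lists rose as well. Their camera adjusted p-values were 0.000384, 0.0095, 0.00382 and 0.00244 (adjusted p = 0.599, 0.599, 0.335 and 0.309 by estimated correlation). The count was 251, 233 higher and 18 lower, and rose to 2163 and 2027 without LR-LR replicates 4 and 5. It was 25, 30, 11, 9 and 21 without LR-HR replicates 1 to 5, 13, 11 and 15 without LR-LR replicates 1, 2 and 3, 439 above the median of all means, 148 after quantile normalization, 164 with trend and robust variance and 3 with only these groups in the fit.

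In the adult hippocampus only 1 transcript was called, Anp32a, which encodes a nuclear phosphoprotein (10.67 ± 0.11 against 9.20 ± 0.19, change 1.46 ± 0.19, adjusted p = 0.00135), with no overlap between the groups. With the replicate block 4 were called, 3 after quantile normalization, 2 with trend and robust variance, 2 without LR-HR replicate 1, 2 without LR-HR replicate 5 and 5 without LR-LR replicate 5. As lists, ribosomal proteins (median 0.37), mitochondrial genes (0.28) and the heat shock and RNA quality list (0.21) rose with camera adjusted p-values of 7.67e-09, 6.9e-05 and 0.0288 (adjusted p = 0.45, 0.492 and 0.508 by estimated correlation). The perineuronal net list (-0.21) and glutamate signalling (-0.11) fell with camera adjusted p-values of 0.0085 and 0.0441 (adjusted p = 0.528 and 0.642 by estimated correlation). No member of these lists was called.

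Averaged over the 4 ages, the foster comparison called 1720 amygdala transcripts (1251 higher and 469 lower). Cartpt rose by 1.28 ± 0.11 (adjusted p = 4.29e-14) and Hbb-b1 by 1.01 ± 0.09. Ttr rose by 0.93 ± 0.19, Mt3 by 0.90 ± 0.08 and the transcription factor Jund by 0.87 ± 0.08. Averages need not hold at each age, and Mt3 and Ttr rose strongly at P14. Tmem255a fell by 0.72 ± 0.17, Ppard by 0.68 ± 0.15 and Erg by 0.65 ± 0.16. In the hippocampus 1346 were called (1036 higher, 310 lower). Zwint, Olfm1 and Tubb2b rose by 1.18 ± 0.25, 1.05 ± 0.21 and 1.05 ± 0.19. The largest falls were Prlh -0.85 ± 0.19, Agmat -0.84 ± 0.19 and Entpd8 -0.81 ± 0.21. After quantile normalization 61.2% of the amygdala calls were higher, against 72.7%, and without replicate 2 the amygdala count was 1047. The hippocampal count was 137, 139, 113 and 2840 without replicates 1, 2, 3 and 5.

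At each age the foster comparison was tested between regions as the amygdala change minus the hippocampal change, each within its own region. Whether the regions came from the same rats is not given in the sources, and the model took them as independent. Ctnnb1 (-2.14 ± 0.38) and Nrn1 (-1.74 ± 0.32) differed at P07 (adjusted p = 0.0142 each). Mt3 (2.09 ± 0.26, adjusted p = 1.77e-05) and Krt14 (4.06 ± 0.56, adjusted p = 4.79e-05) differed at P14. At P21 Chi3l1 (-3.03 ± 0.42, adjusted p = 2.93e-05) and Ndufa11 (2.56 ± 0.37, adjusted p = 5.2e-05) differed. In adults Kcnab2 (2.06 ± 0.28) and Ncdn (1.66 ± 0.23) differed (adjusted p = 3.72e-05 each).

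The number of transcripts whose foster comparison differed between regions was 50 at P07, 561 at P14, 4640 at P21 and 1135 in adults. The share in which the amygdala change was the higher was 32%, 51.2%, 29.7% and 83.4%, and 16.5%, 73.4%, 42.9% and 68.5% after quantile normalization, with 188 transcripts called at P07. Counts without replicates 1 to 5 were 2, 0, 0, 0 and 141 at P07 and 294, 71, 92 (34.8% higher), 139 and 208 at P14. At P21 they were 1136, 268 and 1646 without replicates 1, 2 and 3, and in adults 537, 402, 300 and 433 without replicates 1, 2, 3 and 4. At P07, 104 were called above the median of all means.

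The bred lines themselves were compared as HR against LR pups, each raised by their own mother, so that line and mother differed together. In the amygdala at P07 the alpha globin gene Hba-a3 was 7.39 ± 0.27 in HR and 10.12 ± 0.31 in LR pups (change -2.73 ± 0.21, adjusted p = 9e-07). Ttr fell by 1.93 ± 0.28 (adjusted p = 0.00303) and the lectin gene Clec4b2 by 1.13 ± 0.23 (adjusted p = 0.0486). Pxmp4 rose by 1.43 ± 0.19, Jund by 1.42 ± 0.16, the protease Prss12 by 1.25 ± 0.21 and Egr3 by 0.93 ± 0.18 (adjusted p = 0.00115, 0.000146, 0.0124 and 0.0362). Blood cell genes fell as a list, with 1 of 7 called, Hbb-b1, and 4 by list alone (median -0.54, camera adjusted p = 8.46e-08), and this call held with estimated correlation (adjusted p = 0.00832). Immediate early (median 0.30) and glutamate signalling genes (0.29) rose and choroid plexus genes (-0.21) fell with camera adjusted p-values of 0.0062, 0.00326 and 0.0376 (adjusted p = 0.347, 0.651 and 0.347 by estimated correlation).

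At P07, 29 amygdala transcripts were called between the lines, 24 higher and 5 lower in HR pups, and 83 with the replicate block. The count was 55 without LR replicate 5 and 18 without HR replicate 3, 90 above the median of all means, 80 with trend and robust variance and 12 with only these groups in the fit. The share higher was 82.8% and, after quantile normalization, 61.8%.

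At P14 the amygdala of HR pups had far more myelin and astrocyte transcript than that of LR pups. The myelin genes Mobp and Mbp rose by 3.30 ± 0.34 (adjusted p = 9.72e-07) and 2.68 ± 0.25 (adjusted p = 3.47e-07). Gpnmb, a glycoprotein of activated phagocytes, rose by 3.80 ± 0.96 but spread widely within HR pups (9.72 ± 3.37, adjusted p = 0.0059). Ribosomal protein genes were lower, Rpl39 by 2.45 ± 0.25 and Rpl27 by 2.34 ± 0.24 on the log2 scale, and Tmsb15b2 fell by 2.12 ± 0.63 (adjusted p = 0.0187).

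Myelin genes rose in 13 of 15 members at P14 (median 1.74, camera adjusted p = 3.87e-12; adjusted p = 0.302 by estimated correlation), astrocyte genes in 11 of 15, Gfap by 2.69 ± 0.50 and Gja1 by 1.88 ± 0.19 (camera adjusted p = 3.5e-06; adjusted p = 0.316 by estimated correlation). Without HR replicates 2, 3 and 5, 9 myelin and 6 astrocyte genes were called. All 25 ribosomal protein genes measured fell (median -1.12, camera adjusted p = 8.72e-19; adjusted p = 0.187 by estimated correlation). Mitochondrial genes fell in 10 of 21 and rose in 3 (11 and 3 by list alone; camera adjusted p = 0.000975; adjusted p = 0.626 by estimated correlation). Glutamate signalling rose in 10 of 26 (14 by list alone) and GABA signalling in 9 of 23 (10 by list alone), with 1 lower in each (camera adjusted p = 0.00456 and 0.00747; adjusted p = 0.588 and 0.665 by estimated correlation). The perineuronal net list rose in 8 of 17, histone deacetylases and methyltransferases in 3 of 5 (5 by list alone) and endothelial genes in 3 of 14 (9 by list alone). Their camera adjusted p-values were 0.0035, 0.00883 and 0.00441 (adjusted p = 0.197, 0.223 and 0.347 by estimated correlation).

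At P14, 6 of 14 microglial genes rose (0 without HR replicates 2, 3 and 5) and 1, Aif1, fell (camera adjusted p = 0.0672). Cd74 stood at 8.55 ± 2.36 against 5.76 ± 0.25. Globin genes fell, Hbb-b1 by 1.51 ± 0.22 and Hbb by 0.92 ± 0.19. The oxytocin receptor gene Oxtr fell by 1.29 ± 0.32 (adjusted p = 0.00582) and the stress peptide gene Crh by 0.99 ± 0.30 (adjusted p = 0.0204). The count was 5058 transcripts, 2842 higher and 2216 lower in HR pups. It was 2801 without those HR arrays (43.5% higher, against 56.2%), a setting added after the values were seen.

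At P21 the amygdala difference between the lines had turned, with the ribosomal list higher and GABA, glutamate and myelin lists lower in HR pups. Mt3 rose by 1.71 ± 0.21 (12.50 ± 0.34 against 10.79 ± 0.20), Vax1 and Dmrt1 by 1.76 ± 0.48 and 1.73 ± 0.33 (adjusted p = 0.0169 and 0.00223). Hba-a3 fell (6.39 ± 0.82 against 8.39 ± 0.64), Ptprn2 fell by 1.88 ± 0.24 and Bhlhe40 by 1.87 ± 0.23 (adjusted p = 0.00368, 0.000135 and 0.000107). Ribosomal proteins rose in 18 of 25 members (21 by list alone; camera adjusted p = 9.44e-19; adjusted p = 0.111 by estimated correlation). Glutamate signalling fell in 16 of 26, GABA signalling in 11 of 23 and the perineuronal net list in 5 of 17 (16, 12 and 7 by list alone; camera adjusted p = 0.000142, 2.82e-05 and 0.00857; adjusted p = 0.424, 0.439 and 0.393 by estimated correlation). Myelin genes fell in 8 of 15 (10 by list alone), Mobp by 0.88 ± 0.19 (camera adjusted p = 0.000142; adjusted p = 0.424 by estimated correlation), and mitochondrial genes rose in 6 of 21 and fell in 2 (camera adjusted p = 0.00456; adjusted p = 0.61 by estimated correlation). Among blood markers Hbb rose (14.05 ± 0.39 against 13.04 ± 0.13) and Alas2 fell by 0.90 ± 0.26 (list camera adjusted p = 0.407). The count was 3479, 895 higher and 2584 lower. It was 2242 after quantile normalization, with 47.7% higher against 25.7%.

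Adult HR rats had higher GABA, glutamate and immediate early lists in the amygdala than adult LR rats. Egr3 was 9.62 ± 0.25 against 7.10 ± 0.80 (change 2.52 ± 0.30, adjusted p = 4.61e-06), Cbx6 rose by 2.39 ± 0.22 and Synpo by 2.33 ± 0.26 (adjusted p = 4.38e-07 and 2.27e-06). Or13c7d fell by 1.87 ± 0.26, Rps24 by 1.87 ± 0.19 and Ndufs5 by 1.78 ± 0.18 (adjusted p = 1.88e-05, 1.03e-06 and 8.61e-07). GABA signalling rose in 18 of 23 and glutamate signalling in 15 of 26 with 1 lower (18 and 16 higher by list alone), Grin2b by 2.29 ± 0.24 (camera adjusted p = 3.31e-05 and 2.82e-05; adjusted p = 0.499 and 0.347 by estimated correlation). Immediate early genes rose in 7 of 16 (8 by list alone), Egr1 by 2.04 ± 0.19 (camera adjusted p = 0.00883; adjusted p = 0.424 by estimated correlation), and the perineuronal net list in 10 of 17 (11 by list alone; camera adjusted p = 0.000668; adjusted p = 0.347 by estimated correlation).

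Ribosomal proteins fell in 20 of 25 members in adult HR rats (21 by list alone; median -0.91, camera adjusted p = 7.46e-16; adjusted p = 0.197 by estimated correlation) and mitochondrial genes in 7 of 21, with 3 higher (camera adjusted p = 0.0372; adjusted p = 0.767 by estimated correlation). Myelin genes rose in 7 of 15, astrocyte genes in 10 of 15 with 1 lower, and endothelial genes in 7 of 14 (8, 10 and 8 by list alone; camera adjusted p = 0.0273, 0.0228 and 0.0455; adjusted p = 0.626, 0.651 and 0.651 by estimated correlation). Blood cell genes fell in 2 of 7, Hbb by 1.31 ± 0.18 (camera adjusted p = 0.0233; adjusted p = 0.424 by estimated correlation). The count was 6236, 4486 higher and 1750 lower (71.9% higher, and 58.6% after quantile normalization).

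**Figure D3:**
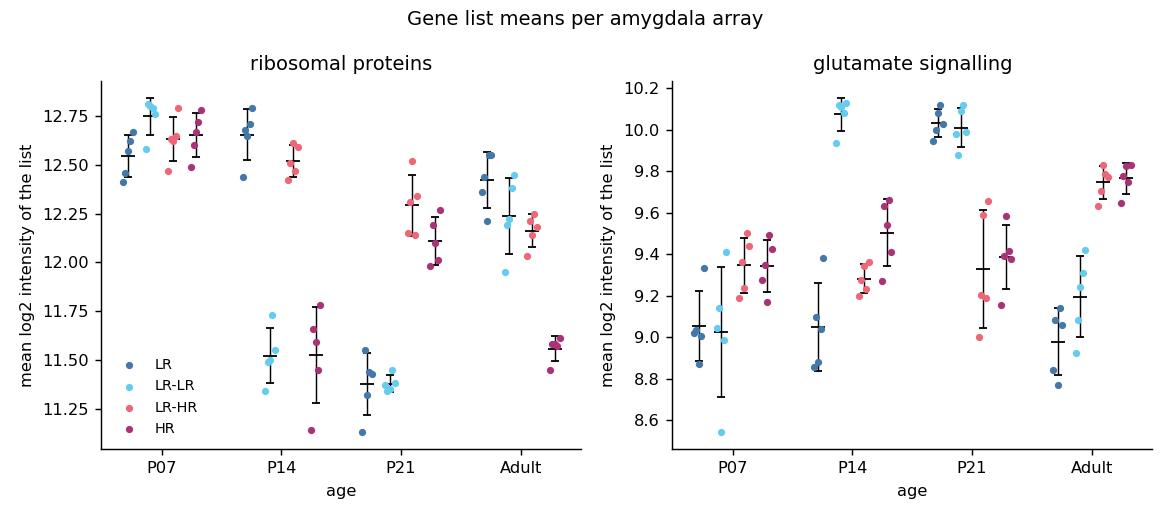
Mean log2 intensity per array of the ribosomal protein and glutamate signalling lists in the amygdala (points) for the 4 rearing groups at each age, with the group mean and SD.

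In the hippocampus at P07, 38 transcripts differed between the lines, 25 higher and 13 lower in HR pups. Hba-a3 was 5.99 ± 0.36, with 3 of 5 HR arrays at or below the random control, against 8.44 ± 0.56 (adjusted p = 0.000768) and Zeb2 fell by 1.28 ± 0.25 (adjusted p = 0.0293). Srebf2 rose by 1.73 ± 0.33, Cxcl12 by 1.39 ± 0.29 and Pam by 1.37 ± 0.23 (adjusted p = 0.0264, 0.0493 and 0.00888). With 0 members called over all transcripts, ribosomal proteins (median -0.41) and blood cell genes (-0.47) fell and astrocyte genes (0.42) and histone modifiers (0.48) rose. Their camera adjusted p-values were 1.1e-07, 0.000309, 0.00456 and 0.00546 (adjusted p = 0.642, 0.071, 0.424 and 0.302 by estimated correlation). Counts were 21, 16 and 13 without HR replicates 1, 2 and 4 and 23 without LR replicate 2 or 4. They were 67 above the median of all means, 68 with trend and robust variance (44.1% higher, against 65.8%) and 6 with only these groups in the fit.

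At P14 the line comparison called 716 hippocampal transcripts, 507 higher and 209 lower. The testis-expressed genes Spetex2c and Spetex2g rose by 1.67 ± 0.29 and 1.52 ± 0.27 and 4930488N24Rikl by 2.13 ± 0.23 (adjusted p = 0.000895, 0.000789 and 1.9e-06). Qdpr fell by 1.47 ± 0.32 and Tomm20 by 1.39 ± 0.31 (adjusted p = 0.00929 and 0.0108). Bdnf, the neurotrophin gene, fell by 0.91 ± 0.24 (adjusted p = 0.0392) and Dnmt1, the maintenance DNA methyltransferase, by 1.05 ± 0.29 (adjusted p = 0.0493). Mitochondrial genes fell with 1 of 21 called, the immature neuron list with 2 of 16, heat shock genes with 1 of 13 and ribosomal proteins with 0 of 25. Their camera adjusted p-values were 5.82e-05, 0.00581, 0.0109 and 0.00594 (adjusted p = 0.651, 0.424, 0.424 and 0.796 by estimated correlation). The count was 1306 without HR replicate 5 (46.9% higher, against 70.8%), 469 without LR replicate 5 and 416 with only these groups in the fit.

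At P21 limma called 0 hippocampal transcripts between the lines, while 1763 had an unadjusted p under 0.05; the count was also 0 with the replicate block, above the median of all means, after quantile normalization, with trend and robust variance and with only these groups in the fit. Myh6, a cardiac myosin gene, had the lowest p of a named gene and did not pass (change 1.37 ± 0.32, adjusted p = 0.724). As lists, myelin (median 0.92), astrocyte (0.81), GABA (0.41), glutamate (0.39), perineuronal net (0.48) and endothelial genes (0.33) rose. Their camera adjusted p-values were 6.85e-06, 6.49e-05, 0.000668, 0.0035, 0.00879 and 0.0398 (adjusted p = 0.316, 0.444, 0.665, 0.651, 0.635 and 0.424 by estimated correlation). Ribosomal proteins (median -0.38) and meningeal genes (-0.42) fell (camera adjusted p = 4.03e-05 and 0.0442; adjusted p = 0.642 and 0.651 by estimated correlation).

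In adult hippocampus 13 transcripts differed between the lines, 7 higher and 6 lower in HR rats. Ifi27, an interferon-induced gene, was 9.41 ± 0.18 against 11.34 ± 0.19 (change -1.93 ± 0.18, adjusted p = 3.48e-06). Pdyn rose by 1.33 ± 0.21, Gfap by 1.20 ± 0.20 and Lrrn1 by 1.19 ± 0.20 (adjusted p = 0.0124, 0.0134 and 0.0145). Astrocyte genes rose with 1 of 15 called (2 by list alone; camera adjusted p = 0.000453; adjusted p = 0.626 by estimated correlation). The list of genes recalled as differing between the bred lines, which is not independent evidence, rose with 0 of 9 called and 2 by list alone (camera adjusted p = 0.0035; adjusted p = 0.347 by estimated correlation). Counts were 7, 6 and 3 without HR replicates 1, 3 and 4 and 4 and 7 without LR replicates 2 and 5. They were 24 above the median of all means, 21 after quantile normalization, 20 with trend and robust variance and 1 with only these groups in the fit.

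Averaged over ages, Hba-a3 was lower in HR rats in both regions, by 1.49 ± 0.16 in the amygdala (adjusted p = 7.88e-11) and by 1.38 ± 0.18 in the hippocampus (adjusted p = 1.62e-07). Amygdala transcripts higher in HR rats included Pik3r1 (1.05 ± 0.15), Mcf2l (0.96 ± 0.09) and the NMDA receptor gene Grin2b (0.94 ± 0.12). Those lower included Or13c7d (-0.81 ± 0.15), Bmp3 (-0.70 ± 0.12) and Rpl36 (-0.69 ± 0.09). In the hippocampus the neuropeptide gene Gal rose by 1.03 ± 0.21, Gfap by 0.90 ± 0.14 and Slc1a3 by 0.84 ± 0.18. Igfbp6 fell by 0.88 ± 0.17, Psmb8 by 0.84 ± 0.16 and Rpl39 by 0.77 ± 0.16. The counts were 3527 in the amygdala (2290 higher) and 346 in the hippocampus (225 higher). Without replicates 2 and 3 the amygdala count was 2189 and 2316, and without replicates 1 to 5 the hippocampal count was 180, 137, 171, 158 and 736, the last with 37.1% higher against 65.0%.

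No transcript was called in the same direction in 6 or more of the 8 region and age strata of the line comparison; 1 was called in 5 strata and 8 in at least 4, out of 22192. Hba-a3 was lower in HR rats in 8 of 8 strata, with a mean change of -1.43, and was called in 3.

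Fostering to a dam of the pup's own line was examined as LR-LR against LR pups. At P14 the amygdala differed in 8364 transcripts, 5535 higher and 2829 lower in LR-LR pups, with Tmem255a higher by 2.89 ± 0.30 (adjusted p = 3.61e-07) and Mt3 lower (9.73 ± 0.36 against 12.53 ± 0.18, adjusted p = 1.05e-08). At P07, 13 were called in the amygdala, Rrad rising by 1.35 ± 0.24 and Ttr falling by 1.64 ± 0.28 (adjusted p = 0.0442 and 0.0404), and 40 with the replicate block. At P21, 3 amygdala transcripts were called, among them Drd2 (1.55 ± 0.23) and Crebbp (-1.60 ± 0.23), each with an adjusted p of 0.00892. In adults 146 were called, Slc16a6 rising by 1.57 ± 0.26 and Nbn falling by 1.71 ± 0.23 (adjusted p = 0.00763 and 0.00213), and 387 with the replicate block. Without LR-LR replicates 1 to 5 the P07 count was 5, 5, 5, 1 and 2, and without LR replicates 1 to 5 it was 7, 2, 2, 0 and 7. At P21 it was 1 and 0 without LR-LR replicates 3 and 5 and 1, 0 and 1 without LR replicates 2, 3 and 5. In adults it was 79 and 93 without LR-LR replicates 2 and 5 and 58 and 67 without LR replicates 4 and 5. Other settings gave 23, 28, 21 and 0 at P07 (above the median of all means, quantile normalization, trend and robust variance, only these groups in the fit), 6 at P21 with trend and robust variance, and 257, 223 and 0 in adults (above the median, quantile normalization, only these groups).

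In the hippocampus LR-LR and LR pups differed in 670 transcripts at P07 (493 higher), 4930488N24Rikl rising by 2.19 ± 0.35 and Ctnnb1 falling by 2.11 ± 0.33 (adjusted p = 0.000234 and 0.00021), and 1663 with the replicate block, the share higher being 73.6% and 63.1% after quantile normalization. At P14 397 differed (284 higher), Dlg4 rising by 1.46 ± 0.31 and Mospd3 falling by 1.27 ± 0.25 (adjusted p = 0.0188 and 0.0153), and 1218 with the replicate block. At P21, 3 fell, among them Mpc1 (-2.18 ± 0.36, adjusted p = 0.025). In adults limma called 0, with 1626 at an unadjusted p under 0.05 and 0 under each other setting run. Without LR-LR replicates 1 to 5 the P14 count was 218, 195, 152, 96 and 160, and without LR replicates 1 to 5 it was 201, 161, 212, 126 and 143. At P14 728 were called above the median of all means. At P21 the count was 224 and 171 without LR-LR replicates 4 and 5, 35 without LR replicate 5, 1 without any of LR-LR replicates 1, 2 and 3 or LR replicates 1, 3 and 4, and 1 with only these groups in the fit.

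The line score asked whether LR-HR pups stood nearer to the HR line than LR-LR pups, at transcripts chosen by the line comparison. In the amygdala LR-HR pups were nearer to HR at P07 (0.18 ± 0.08 against -0.07 ± 0.11), at P21 (0.65 ± 0.15 against -0.58 ± 0.02) and in adults (0.37 ± 0.06 against -0.53 ± 0.09), with exact permutation adjusted p-values of 0.0212, 0.0127 and 0.0127. At P14 they were nearer to LR (-0.56 ± 0.02 against 0.72 ± 0.06, exact permutation adjusted p = 0.0127). In the hippocampus LR-HR scored below LR-LR at P07 (-0.10) and P14 (-0.45, exact permutation adjusted p = 0.0127 each). At P07 LR-HR (0.09) was nearer to HR (0.42) than to LR (-0.70). Differences at P21 (0.36, exact permutation adjusted p = 0.103) and in adults (0.06, 0.0544) did not pass. With 500 transcripts the P07 difference was 0.07, and after quantile normalization it was -0.02 and did not pass. In adults the difference passed with 500 transcripts (0.07), after quantile normalization (0.09) and without LR-LR replicate 4 (0.08). At P21 it passed without LR-LR replicate 4 (0.46) and replicate 5 (0.45), which stood at 0.22 and 0.20 against -0.37, -0.46 and -0.36 in replicates 1 to 3.

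In the amygdala the LR-HR minus LR-LR maturation score was 0.28 at P07, -0.99 at P14, -1.08 at P21 and 0.58 in adults. Each exact permutation adjusted p was 0.0127. From P21 to adults the score fell in LR (1.2 to -0.31) and LR-LR and rose in HR and LR-HR, so age alone does not set it. In the hippocampus LR-HR was higher at P21 (1.36 ± 0.08 against 0.62 ± 0.47, adjusted p = 0.0127). LR-LR replicates 1 to 3 stood at 0.40, 0.13 and 0.30 and replicates 4 and 5 at 1.13 each. This difference no longer passed without LR-HR replicate 1, 3, 4 or 5 (0.73, 0.72, 0.73 and 0.76). Differences at P07 (-0.05), P14 (0.15) and in adults (0.06) had exact permutation adjusted p-values of 0.58, 0.0847 and 0.611. With 100 transcripts those at P07 (-0.19) and P14 (0.18) passed. That at P14 also did without LR-HR replicate 2 (0.19) or LR-LR replicate 5 (0.18).

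**Figure D4:**
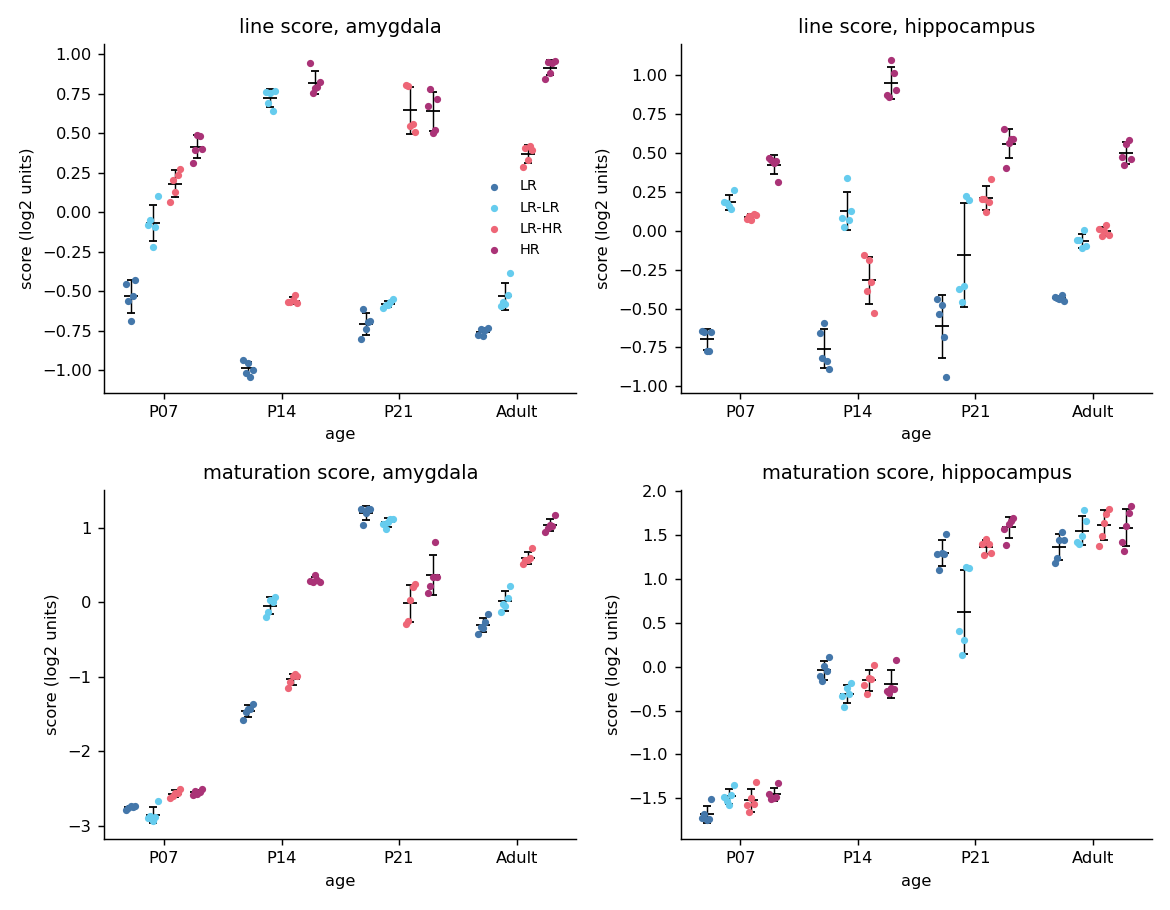
Line score and maturation score (log2 units) of each array by age and rearing group, in the amygdala and hippocampus. The line comparison chose the line score transcripts, so LR and HR separate by construction. LR-HR and LR-LR arrays (means -0.56 and 0.72 in the amygdala at P14) entered that choice only by their variance.

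A panel of 8 stress, social and plasticity genes was called in 4 of 64 tests in the foster comparison. These were Bdnf (1.15 ± 0.25, adjusted p = 0.00183), Fgf2 (1.15 ± 0.38, adjusted p = 0.0318) and Dnmt3a (-0.80 ± 0.20, adjusted p = 0.00584) in the amygdala at P14, and Dnmt3a there at P21. The glucocorticoid receptor gene Nr3c1 ranged from -0.36 to 0.26 over strata with a lowest adjusted p of 0.436, the vasopressin receptor gene Avpr1a from -0.50 to 0.38 (lowest adjusted p = 0.346), Crh from -0.21 to 0.60 (0.168), Oxtr from -0.43 to 0.45 (0.351) and Dnmt1 from -0.31 to 0.88 (0.124). In the line comparison 5 of 64 tests were called. Besides Crh, Oxtr, Bdnf and Dnmt1 this was Dnmt3a in the amygdala at P21 (-0.63 ± 0.20, adjusted p = 0.041). Nr3c1, Avpr1a and Fgf2 were not called between the lines, with lowest adjusted p-values of 0.454, 0.585 and 0.552. Nr3c1 and Avpr1a lay near the random control in the hippocampus (Nr3c1 at or below it in 4 of 5 HR and 3 of 5 LR arrays at P14), so the missing calls there say nothing about these genes.

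Of the 31 gene lists, 12 were not called as lists by camera in any stratum of either comparison. For the foster and line comparisons their lowest adjusted p-values were 0.238 and 0.174 for social and stress neuropeptides, 0.129 and 0.0892 for glucocorticoid receptors and targets, 0.21 and 0.645 for serotonin signalling and 0.129 and 0.127 for dopamine and noradrenaline signalling. They were 0.305 and 0.0702 for DNA methylation, 0.15 and 0.135 for growth factors, 0.428 and 0.183 for the cell cycle, 0.117 and 0.0672 for microglia and 0.0647 and 0.248 for ependyma. For hippocampal neurons they were 0.129 and 0.511, for amygdala neurons 0.271 and 0.289, and for thalamus and habenula 0.0878 and 0.168. The recalled list was not called in the foster comparison (lowest adjusted p = 0.382).

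Changes over age were averaged over rearing groups. From P07 to P14 the myelin genes Cldn11 and Mobp rose in the amygdala by 3.28 ± 0.13 and 2.49 ± 0.15, and Cd24 (-2.17 ± 0.11) and Pafah1b3 (-1.75 ± 0.10) fell. From P14 to P21 Mobp rose further by 2.23 ± 0.15, but not in HR (11.64 to 11.12). Dpysl3, of axon growth, and Ttr fell by 2.01 ± 0.10 and 1.86 ± 0.19. From P21 to adult, Ptgds (1.92 ± 0.29) and Or10d4b (1.38 ± 0.36) rose and Alox15 (-2.15 ± 0.12) and Hbb (-1.49 ± 0.08) fell. In the amygdala 6128, 3390 and 4366 transcripts changed over the 3 steps; the count was 2143 for the second step without replicate 4 and 2797 for the third without replicate 3.

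In the hippocampus the interneuron gene Pvalb rose by 1.88 ± 0.15 from P07 to P14 and S100b by 1.81 ± 0.18, while Dpysl3 and Crmp1 fell by 1.81 ± 0.15 and 1.74 ± 0.20. Between P14 and P21 Cldn11 and Mobp rose by 2.92 ± 0.21 and 2.89 ± 0.18 and Fabp7 and Tubb2b fell by 1.79 ± 0.15 and 1.66 ± 0.19. From P21 to adult Ptgds and Qdpr rose by 2.05 ± 0.17 and 1.74 ± 0.18 and the globin genes Hbb-b1 and Hbb fell by 1.70 ± 0.16 and 1.64 ± 0.15. The steps called 3146, 5225 and 3924 hippocampal transcripts. The second count was 3127 without replicate 4, and the third was 2360, 2176 and 2191 without replicates 1, 2 and 3. Adjusted p-values of the genes named for these steps ran from 1.67e-33 for Cldn11 to 0.00367 for Or10d4b.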

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

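The splits of the arrays given here were chosen as tests only after the counts had been seen. Within each group of 5 arrays the value lying farthest from the others was examined by Dixon's ratio for the scores and for the genes of the panel and of the largest changes. Chance flags about 1 in 20 groups, which is 22.7 of the 454 groups examined, and 34 were found (7.49%). None was left out.

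In the foster comparison in the amygdala these were the maturation score of LR-LR replicate 5 at P07 (-2.661), Bdnf in LR-LR replicate 3 at P14 (9.202), and at P21 Rplp1 in LR-LR replicate 5 (10.15), Abhd14b (7.672) and Erg (7.549) in LR-HR replicate 5 and Nr3c1 in LR-LR replicate 3 (7.55). In adults they were Haao in LR-LR replicate 4 (7.983) and LR-HR replicate 5 (5.387) and Avpr1a in LR-HR replicate 5 (7.161). In the hippocampus they were Zbtb18 in LR-LR replicate 5 (8.975) and Dnmt1 in LR-HR replicate 5 (10.68) at P07, and Mrpl47 in LR-HR replicate 2 (7.717) and Rnf44 in LR-LR replicate 5 (11.32) at P14. At P21 they were Il7 in LR-LR replicate 1 (8.163) and LR-HR replicate 1 (6.752) and Crh in LR-LR replicate 1 (8.35). In adult hippocampus they were Nr3c1 in LR-HR replicate 5 (6.556), Bdnf in LR-HR replicate 1 (8.672), Fgf2 in LR-LR replicate 5 (7.67) and Dnmt3a in LR-LR replicate 5 (9.528) and LR-HR replicate 5 (9.175).

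In the line comparison the amygdala values were Clec4b2 in HR replicate 2 (5.415) and Oxtr in HR replicate 5 (7.442) at P07, and at P14 Rpl39 (7.985) and Nr3c1 (5.396) in HR replicate 1 and Tmsb15b2 in LR replicate 4 (6.702). At P21 they were Dnmt1 in LR replicate 1 (10.96) and Dnmt3a in HR replicate 3 (10.94), and in adults Egr3 in HR replicate 1 (9.195) and Crh in LR replicate 1 (9.29). The hippocampal values were Dnmt1 (10.28) and Dnmt3a (10.56) in LR replicate 5 at P07, and Bdnf in HR replicate 1 (7.537) and Dnmt1 in LR replicate 3 (9.958) at P14.

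The foster comparison differed between regions for 50, 561, 4640 and 1135 transcripts at P07, P14, P21 and in adults. The leading genes were Ctnnb1 (-2.14) and Nrn1 (-1.74), Mt3 (2.09) and Krt14 (4.06), Chi3l1 (-3.03) and Ndufa11 (2.56), and Kcnab2 (2.06) and Ncdn (1.66).

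The arrays of each comparison were also divided in other ways, 100 splits with the real one included, to see whether chance could give the counts. In the foster comparison in the amygdala 1 of 100 splits called as many at each age, the real counts being 20, 4943, 4797 and 4817 and the highest others 2, 311, 0 and 4199. In the hippocampus 2, 1, 4 and 2 of 100 did, for 754, 151, 251 and 1 transcripts, with highest others of 1137, 0, 3127 and 1. In the line comparison in the amygdala 1 of 100 did at each age (29, 5058, 3479 and 6236, highest others 2, 1883, 52 and 2383), and in the hippocampus 1, 1, 100 and 2 of 100 did (38, 716, 0 and 13, highest others 1, 100, 2 and 910). In the fostering comparison 2, 1, 1 and 2 of 100 did in the amygdala (13, 8364, 3 and 146, highest others 21, 4273, 0 and 326) and 1, 1, 11 and 100 of 100 in the hippocampus (670, 397, 3 and 0, highest others 163, 1, 2803 and 764).

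For the foster by region interaction 4, 2, 1 and 1 of 100 splits called as many (50, 561, 4640 and 1135, highest others 420, 2880, 478 and 0). For the averages over ages 2 and 2 of 100 did in the foster comparison (1720 and 1346, highest others 2379 and 2430) and 1 and 1 in the line comparison (3527 and 346, highest others 1681 and 13). For the developmental steps 1, 1 and 2 of 100 did in the amygdala (6128, 3390 and 4366, highest others 292, 2645 and 5957) and 1, 1 and 1 in the hippocampus (3146, 5225 and 3924, highest others 23, 1491 and 2492). Under 5 in 100 splits called as many for 35 of 36 counts above 0, all but the fostering comparison in hippocampus at P21. Same-numbered arrays correlated positively in 110 of 120 pairs, so arrays are not exchangeable and chance is not excluded. Where 0 were called every split calls as many, so the splits decide nothing. In 13 comparisons another split called more than the real one. It called several times as many in the hippocampus in the foster comparison at P21, the fostering comparison at P21 and in adults and the line comparison in adults, and for the interaction at P07 and P14, which points to a structure of the samples; its source was not tested. Where numbers paired the arrays only 16 splits part all pairs, too few to exclude chance. The highest other count among these was 0 in the foster comparison (real counts 4817 in adult amygdala and 754 and 1 in hippocampus at P07 and in adults), 2 in the line comparison (29 in amygdala at P07) and 2, 2, 0 and 0 in the fostering comparison (13 and 146 in amygdala at P07 and in adults, 670 and 397 in hippocampus at P07 and P14).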

How the results depend on the processing

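The ribosomal protein mean as a covariate and the fit without HR P14 arrays 2, 3 and 5 were tests chosen only after the results had been seen, those 3 arrays being named because of their Cd68 and Gfap values. A count is given here where a setting moved it more than 1.5-fold; the cause was not tested. The main limits are 5 arrays per group, litters that are not given, regions normalized separately so that the regions were not compared with each other averaged over ages and no alternatives to that comparison were run, and signal over background, which was known only from a random sequence control in the hippocampus (mean 59.3, with 4.04% of hippocampal transcripts at or below it), so low transcripts may carry little signal.

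With the replicate block 18 of 40 counts moved, all up. In the foster comparison the blocked counts were 404 at P07 in the amygdala and 2263, 488, 695 and 4 in the hippocampus at P07, P14, P21 and in adults. In the fostering comparison they were 40 and 387 in the amygdala at P07 and in adults and 1663 and 1218 in the hippocampus at P07 and P14. In the line comparison they were 83 in the amygdala at P07 and 665, 1482 and 53 in the hippocampus at P07, P14 and in adults. For the foster by region interaction they were 97, 863 and 2019 at P07, P14 and in adults, and for the averages over ages in the hippocampus 3362 (foster) and 799 (line). Arrays of the same number correlated at a median r of 0.151 and others at -0.0411, and 168 of 240 arrays correlated best with their own number. Every array did so in the foster comparison at P07 in both regions, in the line comparison in the hippocampus at P07 and in the fostering comparison in the amygdala at P07 and in adults and in the hippocampus at P07 and P14. The block changed no other call where the numbers paired; of list calls it ended those of mitochondrial genes in adult amygdala and of meningeal genes in the hippocampus at P21, both in the line comparison (adjusted p = 0.0592 each).

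Among the transcripts above the median of all means, 10 of 40 counts moved, 9 up and 1 down: 199 in the foster comparison in the amygdala at P07 and 439 in the hippocampus at P21; 23 and 257 in the fostering comparison in the amygdala at P07 and in adults and 728 in the hippocampus at P14; 90 in the line comparison in the amygdala at P07 and 67 and 24 in the hippocampus at P07 and in adults; 104 for the interaction at P07; and 27 list calls in the line comparison. With quantile normalization of the arrays of the fit 7 of 38 moved, 5 up and 2 down: 148 and 3 in the foster comparison in the hippocampus at P21 and in adults, 28 and 223 in the fostering comparison in the amygdala at P07 and in adults, 2242 in the line comparison in the amygdala at P21, 21 in the hippocampus in adults, and 188 for the interaction at P07. With trend and robust variance 8 of 38 moved, 7 up and 1 down: in the foster comparison 150 in the amygdala at P07 and 164 and 2 in the hippocampus at P21 and in adults, in the fostering comparison 21 and 6 in the amygdala at P07 and P21, and in the line comparison 80 in the amygdala at P07 and 68 and 20 in the hippocampus at P07 and in adults. With only the 2 groups in the fit 10 of 24 moved, all down: in the foster comparison 0 in the amygdala at P07 and 5 and 3 in the hippocampus at P14 and P21, in the fostering comparison 0 and 0 in the amygdala at P07 and in adults and 1 in the hippocampus at P21, and in the line comparison 12 in the amygdala at P07 and 6, 416 and 1 in the hippocampus at P07, P14 and in adults.

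With the ribosomal protein mean as covariate 10 of 16 counts moved, 6 up and 4 down: in the foster comparison 380, 3287, 43 and 7581 in the amygdala from P07 to adults and 2225, 792 and 1079 in the hippocampus at P07, P14 and P21, and in the line comparison 2358 and 1 in the amygdala at P14 and P21 and 2746 in the hippocampus at P07. In the amygdala at P14 and P21 the ribosomal means of the compared groups did not overlap, nor in adults in the line comparison, so the covariate stood in for the group there and those counts say nothing on stability. With HR P14 arrays 2, 3 and 5 left out the line comparison in the amygdala at P14 called 2801. With the inter-gene correlation estimated from the data 2 list calls of 47 stayed in the foster comparison and 1 of 47 in the line comparison.

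Leaving out each array in turn moved 123 of 310 counts, 15 up and 108 down. Where counts moved, they ran in the foster comparison from 4 to 225 in the amygdala at P07 and from 414 to 1369, 28 to 135, 9 to 2163 and 1 to 5 in the hippocampus from P07 to adults. In the fostering comparison they ran from 0 to 7, 0 to 3 and 58 to 164 in the amygdala at P07, P21 and in adults and from 96 to 218 and 1 to 224 in the hippocampus at P14 and P21. In the line comparison they ran from 18 to 55 in the amygdala at P07 and from 13 to 55, 469 to 1306 and 3 to 12 in the hippocampus at P07, P14 and in adults. The interaction ran from 0 to 141, 71 to 294, 268 to 5676 and 300 to 1413, the foster averages from 1047 to 1480 and 113 to 2840, and the line averages from 2189 to 3490 and 137 to 736 (amygdala, then hippocampus). The developmental steps ran from 2143 to 3199 and 2797 to 4140 in the amygdala and from 3127 to 5063 and 2176 to 4660 in the hippocampus (P14 to P21, then P21 to adult).

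The line score at P07 in the hippocampus was reversed with the top 500 transcripts (0.0710, adjusted p = 0.0317) and weaker after quantile normalization within the stratum (-0.0248, adjusted p = 0.317). In adult hippocampus it was stronger with the top 500 (0.0719) and after that normalization (0.0926). The maturation score in the hippocampus was stronger with the top 100 transcripts at P07 (-0.19) and P14 (0.18). Leaving out an array, the hippocampal line score ran from 0.29 to 0.46 at P21 and 0.0498 to 0.0787 in adults, and the hippocampal maturation score from 0.11 to 0.19 at P14 and 0.62 to 0.87 at P21. Of the changes of named genes 0 reversed under any setting; leaving out an array weakened 236 and strengthened 4 of 2660, and only the 2 groups in the fit weakened 38 of 224.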

Other observations

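The comparison of foster with line changes, the label, striatal, age, reactive tissue and choroid plexus tests and the ribosomal part of the axis test were chosen only after the result was seen; the axis test itself and the epidermal markers were set down before. At P21 the amygdala of LR-HR pups had more of several peptide transcripts while most GABA and glutamate signalling genes were lower: Cartpt by 1.60 ± 0.19, Sst by 1.46 ± 0.17 and Cck by 1.05 ± 0.19. In adults the serotonin receptor gene Htr2c was higher by 1.82 ± 0.23 and the orexin gene Hcrt lower by 1.51 ± 0.37 on the log2 scale.

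Foster and line changes in the amygdala share no arrays, and across transcripts they correlated at an r of 0.214 at P07, -0.614 at P14, 0.693 at P21 and 0.68 in adults. In the hippocampus r was 0.182, -0.233, 0.417 and 0.0929.

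In the amygdala at P14 and P21, and in adults in the line comparison, the ribosomal list differed in the opposite direction to the GABA and glutamate lists; in the adult foster comparison ribosomal proteins were not called. A hypothesis of RNA quality or labelling may account for part of it, as the leading within-group component of hippocampal arrays correlated with all 6 amygdala contrasts (lowest absolute r 0.345). What this component stands for is not known, as replicate number explained 76.6% of it. For the ribosomal part RNA quality cannot be told apart from other causes, as its mean loading of 0.283 lay on the glutamate list's side of 0 (0.996) but under the median of the lists (0.506). Striatal tissue in the dissection does not account for the line contrast at P21, where the striatum list had a median of 0.0837 and the glutamate list -0.788. In the other 5 contrasts striatal tissue cannot be told apart from other causes, as the striatum list had the larger median in size in 2 of them (-1.10 against -0.79 in the foster contrast at P14 and 1.42 against 0.66 in adults). Exchanged LR-LR and LR-HR labels at P14 cannot be told apart from a true difference (r = -0.614 in the amygdala and -0.233 in the hippocampus). LR with LR-HR at P14, and LR with LR-LR and LR-HR with HR at P21, had like ribosomal means; hybridisation batches are not given in the sources used here, and an effect of the foster dam stays open and untested.

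Myelin and glial transcripts were high in HR pups at P14 in the amygdala. Older animals in that group cannot be told apart from a line difference, as the tests parted: transcripts falling from P14 to P21 stood at 21.9% of the way (SD 25.1, HR replicate 1 at 66.5% and the others from 5.8% to 14.6%), and the maturation score at 66.1%. A hypothesis of reactive tissue in HR replicates 2, 3 and 5 cannot be told apart from a line difference. Without those arrays, named for their Cd68 and Gfap values, the myelin median kept 66.5% and the microglial 4.34% of its value. A difference between the lines stays open and untested.

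Krt14, Krt5, Krt15 and Krt27, keratins picked from the calls, were higher in LR-HR than in LR-LR pups at P14 in the amygdala, Krt14 by 3.43 ± 0.41. Krt15 was also high in LR pups (8.17 against 7.90 in LR-HR), and 0 of 5 keratins not looked at before were called. A hypothesis of skin or hair carried into the tissue cannot be told apart from other causes: 15 of 47 epidermal markers were measured, with a median of 0.894 and 3 called higher, among them Cst6, which was as high in LR (9.41) as in LR-HR pups (9.42). Choroid plexus carried into the tissue cannot be told apart either (median 0.243 without Ttr). An effect of the foster dam stays open and untested.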
